A study of Mus musculus with 48 samples.

How the data were processed

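Expression was measured by RNA sequencing of sorted nociceptors from 16 combinations of animal and side, each as 3 technical aliquots, which gave 48 libraries. Per the labels' protocols, ganglia were taken 3 days after a forceps crush of the sciatic nerve, dissociated enzymatically and sorted for the reporter. Per the same protocols, each library was made from about 100 cells with a SMARTer Ultra Low RNA kit and sequenced as single reads of 50 bases. That kit does not mark strand, so reads of overlapping antisense genes cannot be told apart, and no molecular identifiers are named, so counts include amplification copies. Mice were of a mixed C57BL/6 and AJ background, with 2 animals of each sex per group.

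The authors deposited a table of whole-number read counts per Ensembl gene for each library. Per the submitters' processing notes the tools were FastQC, STAR, HTSeq and DESeq2 on mm10, with versions not given in the sources used here. The counts are not normalized, and their 47643 gene identifiers include 47224 that matched a symbol in the GENCODE M21 annotation of the same assembly, from which coordinates were taken, and 419 that did not. Counts at the end of each deposited file in 5 HTSeq summary lines stayed out of library sizes and tests. Of gene counts and summary lines together, the line for alignments to several places made up 37.488 to 46.12%. The line for reads outside genes made up 5.921 to 19.368% and that for ambiguous reads 1.915 to 2.576%. Since reads with several alignments were not counted, genes with near-identical copies, such as ribosomal protein genes, have uncertain levels. The authors also deposited a table of log2 fold changes with standard errors and p-values from DESeq2 for 3 comparisons, per the file headers and the submitters' processing notes. The model and the reference group are not given in the sources used here. It was used only to set its calls beside those computed here.

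Counts of the 3 aliquots were summed per animal and side, since the labels call them technical replicates, so the replicate is the animal (n = 4 per group). Aliquots of an animal differed by more than sampling noise, with a chi-square per degree of freedom of 18.1 to 165 between them. The median correlation of log2 CPM between aliquots of an animal was 0.907, 0.964, 0.924 and 0.908 in uninjured control, uninjured cKO, crush control and crush cKO samples. The median variance across genes was 0.131 between aliquots and 0.0592 between animal means. Genes detected per library ranged from 15493 to 20466, the share of the 10 most abundant genes from 7.77 to 11.9% and that of mitochondrially encoded genes from 0.892 to 3.37%. Sex-linked genes matched the sex label in 48 of 48 libraries.

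Summed counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (19048 genes kept) and 1 mean per group, by the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. The 5 contrasts were crush in control, crush in cKO, deletion in uninjured neurons, deletion after crush, and the interaction of crush and deletion. Crushed cKO samples were also set against uninjured control samples, only for comparison with the deposited table. The SE of a log2 change was taken as its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. The 27 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01), with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. They were regeneration-associated genes, peptidergic and non-peptidergic nociceptor markers, ion channels, inhibitory and modulatory receptors, presynaptic release genes and axon cytoskeleton genes. Further lists were mTORC1 pathway members, the ATF4 amino acid response, endoplasmic reticulum chaperones, glycolysis and hypoxia-inducible genes and the pentose phosphate pathway. Others held genes of sterol and lipid synthesis, lysosome and TFEB targets, cytosolic ribosomal proteins, nuclear and mitochondrially encoded oxidative phosphorylation, and interferon-induced, immediate early and cell cycle genes. The last 7 held markers of large-fibre neurons, satellite glia, Schwann cells, macrophages, neutrophils and lymphocytes, vascular cells and fibroblasts, and erythrocytes. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined. That rule took Tsc2; then, among called genes with a mean CPM of at least 10 and no overlap between the groups' animals, the 10 largest rises and falls (5 for the interaction, without the condition on overlap); and from each list up to 4 called members with the smallest p, or up to 2 abundant members as values.

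On counts simulated from the real means, with 200 of 19048 genes changed, 88% of 4-fold changes and 30.0% of 2-fold changes were recovered for crush in control neurons. The shares were 86% and 44% for crush in cKO neurons, 82% and 48% for deletion in uninjured neurons, 84% and 44% for deletion after crush and 72% and 32% for the interaction, with 2 to 5 false calls each. Changes of 1.5-fold were recovered in 0 to 20.0% of cases. The simulation changed far fewer genes than most of the real comparisons called, such as 3750 for crush in control neurons, 1710 of them over 2-fold. The Benjamini-Hochberg cutoff is laxer where more genes change, so these shares do not measure the reach of the real fits.

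Animals carry the numbers 1 to 4 in each group, and the labels do not say whether equal numbers in the uninjured and crush groups of a genotype are both sides of an animal. Deviations from the group mean correlated across genes between same-numbered samples at 0.275, 0.148, 0.387 and 0.146 in control and 0.287, 0.436, 0.330 and 0.282 in cKO animals, all above 0.1. By that threshold the numbers were taken to pair the samples within a genotype, and a fit with the pair as a block was set beside the unpaired one. Same-numbered samples also share their sex, and with sex removed the lowest of these correlations was -0.118 in control and 0.0823 in cKO animals. Control animals 2 and 4 correlated more with the other number of their sex (0.180 and 0.227), so the pairing of the control samples is uncertain. Alternatives were DESeq2 1.42.0 size factors and its Wald test, TMM without mitochondrial and the most abundant genes, and other filters. Others were a sex or glial covariate, thinned aliquots, stricter thresholds, and leaving out each sample in turn. A further fit took the 48 libraries as separate samples, which counts technical aliquots as replicates. Limma-voom was run on the libraries with each animal and side as a random block (consensus correlation of aliquots 0.0781). That block does not join the 2 sides of an animal. No deposited library was left out, and tables and figures were made with Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.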

Results

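RNA was sequenced from nociceptors, the sensory neurons that respond to damaging stimuli. In the mice they came from, the sciatic nerve of one side had been crushed 3 days earlier. Neurons came from the fourth lumbar dorsal root ganglion and were sorted by ZsGreen, a fluorescent protein switched on by Cre recombinase from the Nav1.8 (Scn10a) locus. The same Cre deleted Tsc2, which encodes tuberin, the protein that restrains the growth-promoting kinase complex mTORC1. Control animals lost 1 of the Tsc2 copies in these neurons and conditional knockout (cKO) animals lost both. Ganglia of the crushed side were compared with contralateral, uninjured ganglia, which gave 4 groups of 4 animals. Each animal and side was represented by 3 technical aliquots of about 100 cells. The 48 libraries held 5159353 to 34228180 counts assigned to genes (median 16885996). The 16 samples obtained by summing aliquots held 36773198 to 63365268. In principal component analysis of the summed samples the first component carried 27.5% of the variance and the second 12.3%. Below, a gene is said to have risen or fallen only if its adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was under 0.05 among 19048 genes tested. Log2 changes are given ± SE.

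Tsc2 itself (ENSMUSG00000002496; chromosome 17, 24595816 to 24632630, minus strand, mm10) was lower in every cKO sample than in every control sample of the same side. Uninjured control samples had 21 ± 5.14 CPM (counts scaled to library size; SD, n = 4) and uninjured cKO samples 8.86 ± 1.51, a log2 change of -1.24 ± 0.23 (edgeR adjusted p = 0.00101). After crush the levels were 23.2 ± 3.76 CPM in control and 8.3 ± 2.42 CPM in cKO samples, a log2 change of -1.48 ± 0.23 (adjusted p = 0.00106). The exact two-sided permutation test gave p = 0.0286 for either side, the smallest value that 4 against 4 animals allow. Crush changed Tsc2 in neither genotype past the threshold, with log2 changes of 0.14 ± 0.22 in control (adjusted p = 0.723) and -0.09 ± 0.23 in cKO samples (adjusted p = 0.914). The gene-level count covers exons outside the deleted part as well, so the remaining counts do not measure intact transcript.

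**Figure D1:**
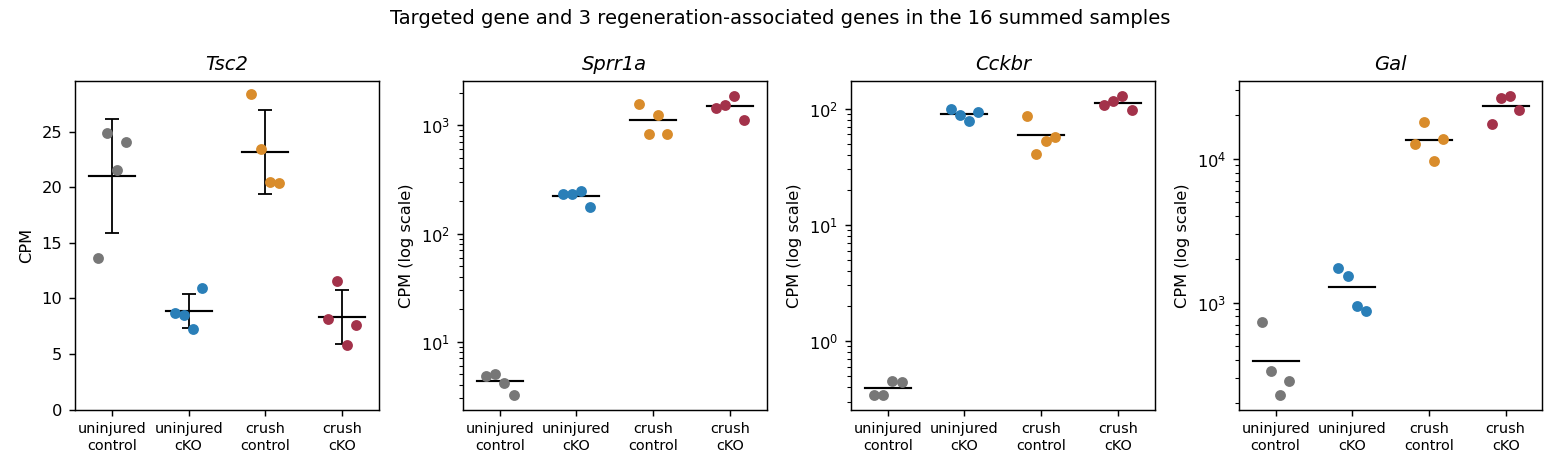
CPM of Tsc2 (linear axis; bars, mean ± SD) and of the injury-induced genes Sprr1a, Cckbr and Gal (log axes; bars, mean) in each of the 16 summed samples, 4 animals per group. Tsc2 was lower in both cKO groups, and Sprr1a and Cckbr stood above the uninjured control samples in the other 3 groups.

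The first comparison asked which genes a peripheral nerve injury changes in control nociceptors. Crush raised genes induced in regenerating sensory neurons from low levels. Sprr1a, a small proline-rich protein of regenerating axons, went from 4.31 ± 0.8 to 1119.6 ± 359 CPM (SD, n = 4), a log2 change of 8.02 ± 0.28 (adjusted p = 1.83e-11). The cholecystokinin receptor gene Cckbr rose by 7.22 ± 0.24, Sez6l by 7.55 ± 0.28, the activin subunit gene Inhbb by 7.06 ± 0.24 and the adhesion gene Flrt3 by 4.22 ± 0.14 on the log2 scale. Among the largest falls were Kcnmb1, an auxiliary subunit of large-conductance potassium channels, at -2.59 ± 0.57, Dpp10, an auxiliary subunit of A-type potassium channels, at -2.66 ± 0.46, and the transcription factor gene Etv1 at -2.60 ± 0.59. In all, 3750 genes changed, 2097 upwards and 1653 downwards, and 1710 of them by more than 2-fold.

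Of the 39 measured regeneration-associated genes 37 rose and 0 fell after crush in control neurons (39 rose when adjusted over the list alone; camera adjusted p = 1.17e-44). The amino acid response driven by the transcription factor ATF4 moved the same way, with 27 of 36 members up and 1 down (29 up adjusted over the list alone; camera adjusted p = 4.18e-15). Its members included Atf4 itself (1.55 ± 0.11), the alanyl-tRNA synthetase gene Aars (1.74 ± 0.11) and the glutathione-degrading enzyme gene Chac1 (3.41 ± 0.27). Axon cytoskeleton genes rose in 14 and fell in 3 of 32 cases (16 up and 4 down adjusted over the list alone), led by the tubulin genes Tubb6 (5.10 ± 0.32) and Tuba1c (3.48 ± 0.27). Their camera adjusted p was 7.39e-05, and 0.103 with an estimated correlation. Ion channels of excitability and transduction fell in 14 and rose in 5 of 42 cases (21 down adjusted over the list alone; camera adjusted p = 0.00196, and adjusted p = 0.158 with an estimated correlation). The nociceptor sodium channel genes Scn10a (-0.93 ± 0.17) and Scn9a (-0.70 ± 0.13) and the potassium channel gene Kcna2 (-1.37 ± 0.17) fell, and the calcium channel subunit gene Cacna2d1 rose (adjusted p = 3.09e-06). Nuclear-encoded oxidative phosphorylation genes fell in 27 and rose in 2 of 70 cases, with Ndufb3 at -0.71 ± 0.12 (38 down adjusted over the list alone). This list had a camera adjusted p of 2.71e-08, and of 0.524 with an estimated correlation.

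Inhibitory and modulatory receptors fell in 6 of 23 cases (11 adjusted over the list alone; camera adjusted p = 0.0105, and adjusted p = 0.07 with an estimated correlation). Peptidergic nociceptor markers fell in 4 and rose in 1 of 11 cases (camera adjusted p = 0.039, and p = 0.524 with an estimated correlation). Of the 17 non-peptidergic and pruriceptor markers 1 rose while the list as a whole lay lower (median -1.41; p = 0.0435, and p = 0.558 with an estimated correlation). Cytosolic ribosomal protein genes rose in 4 of 75 cases (camera adjusted p = 0.0435; adjusted p = 0.799 with an estimated correlation), as uncertain values because these genes share reads with processed copies. Mitochondrially encoded genes fell in 2 of 7 cases (p = 0.0407, and p = 0.58 with an estimated correlation). No camera call was made for presynaptic release genes (4 up and 7 down of 28, with Snap25 at -1.04 ± 0.14 and Pclo at -0.70 ± 0.09; adjusted p = 0.388). The same held for mTORC1 pathway members (6 up, 5 down of 24; p = 0.672) and endoplasmic reticulum chaperones (3 up, 5 down of 20; p = 0.787). Nor was one made for glycolysis and hypoxia-inducible genes (4 up, 4 down of 23; p = 0.65), although the glucose transporter gene Slc2a1 rose by 2.19 ± 0.15. The pentose phosphate pathway had 2 of 7 genes up (p = 0.0544). Sterol and lipid synthesis genes (7 up of 27, with Fasn at 1.05 ± 0.17; p = 0.0544), lysosome and TFEB targets (4 up, 1 down of 33; p = 0.787) and cell cycle genes (2 up of 16; p = 0.672) also missed the threshold. So did interferon-induced (1 up, 1 down of 19; p = 0.65) and immediate early genes (1 down of 14; p = 0.787). Beside these changes, markers of other cells moved as follows. Large myelinated-fibre neuron markers fell in 3 of 10 cases (p = 0.0593), satellite glia markers changed in none of 11 (p = 0.388), and of 11 Schwann cell markers 1 fell (p = 0.787). Macrophage markers rose in 2 of 12 cases (Cx3cr1 at 7.64 ± 0.61; p = 0.362), vascular and fibroblast markers in 2 of 15 (p = 0.269) and erythrocyte markers in none of 3 (p = 0.468). Neutrophil and lymphocyte markers rose in 2 of 3 cases, with the T cell receptor gene Trbc2 going from 0.0191 ± 0.0165 to 4.71 ± 1.13 CPM (camera adjusted p = 0.0435; adjusted p = 0.158 with an estimated correlation and 0.0876 with the replicate block).

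The second comparison asked for the crush response of neurons that lacked both Tsc2 copies. Of the 490 genes that crush raised in cKO neurons, 389 had also risen with crush in control neurons. Gal, the neuropeptide galanin, rose from 1272 ± 431 to 23249.5 ± 4608 CPM (SD, n = 4), a log2 change of 4.19 ± 0.36 (adjusted p = 1.18e-05). The annexin gene Anxa1 rose by 4.06 ± 0.39, Sprr1a by 2.75 ± 0.22 and Lmo7 by 2.44 ± 0.19. The serotonin transporter gene Slc6a4 (3.23 ± 0.49), the arginase gene Arg2 (3.52 ± 0.64), the pro-apoptotic gene Pmaip1 (4.04 ± 0.77) and the metalloproteinase inhibitor gene Timp1 (2.94 ± 0.58) were also among the largest rises. Kcnmb1 (-3.30 ± 0.59), the angiotensin receptor gene Agtr1b (-2.90 ± 0.43) and the sodium channel genes Scn11a (-2.04 ± 0.40) and Scn10a (-1.19 ± 0.17) fell. The Kcnmb1 level of crush cKO animal 4 stood apart from the other 3 at 10.5 CPM. In all, 1034 genes changed, 490 upwards and 544 downwards, 457 of them by more than 2-fold. The falls called after crush in control neurons as well numbered 380, and independent lists would share 53.9 rises and 47.2 falls.

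Regeneration-associated genes rose in 22 of 39 cases in cKO neurons (27 adjusted over the list alone; camera adjusted p = 3.84e-26), and none fell. Members of the ATF4 response rose in 8 of 36 cases (15 adjusted over the list alone; camera adjusted p = 6.58e-10, and adjusted p = 0.0728 with an estimated correlation). Atf4 rose by 0.55 ± 0.11 and the mitochondrial folate enzyme gene Mthfd2 by 0.75 ± 0.13. Axon cytoskeleton genes rose in 9 and fell in 3 of 32 cases, with Tubb6 at 1.64 ± 0.28 and the growth cone gene Stmn2 at 0.60 ± 0.10 (17 up adjusted over the list alone). The camera adjusted p was 5.73e-05 for them, and 0.129 with an estimated correlation. Ion channels fell in 8 and rose in 2 of 42 cases (p = 0.0382; p = 0.43 with an estimated correlation). Of 17 non-peptidergic and pruriceptor markers 3 fell and 1 rose (p = 0.00698; p = 0.43 with an estimated correlation). Interferon-induced genes rose in 4 and fell in 1 of 19 cases (8 up adjusted over the list alone; camera adjusted p = 0.00089, and adjusted p = 0.43 with an estimated correlation). Among the rises were the antiviral genes Bst2 (2.57 ± 0.39) and Isg15 (2.12 ± 0.46). Immediate early genes rose in 1 of 14 cases (p = 0.0254; p = 0.43 with an estimated correlation) and ribosomal protein genes in 4 of 75 (p = 9.77e-06; p = 0.43 with an estimated correlation). Oxidative phosphorylation genes lay lower as a list with no member called (median -0.09; p = 0.00698, and p = 0.61 with an estimated correlation). No member of the lysosome list changed (camera adjusted p = 0.296). Beside these groups, satellite glia markers lay higher as a list with none of 11 called (median 0.48; p = 0.00089, and p = 0.43 with an estimated correlation). Trbc2 rose by 2.34 ± 0.38, as 1 of 3 neutrophil and lymphocyte markers (p = 0.0218; p = 0.129 with an estimated correlation). The number of calls fell to 618, 642 and 683 without the uninjured cKO sample of animal 1, 2 or 3 and to 637 without the crush cKO sample of animal 4. With the mean of glial markers as a covariate it was 668, with DESeq2 1782 and with limma-voom 1563.

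Whether crush acted differently in the 2 genotypes was tested by the interaction of crush and genotype. Several genes that crush raised in control neurons had a smaller crush effect on the log2 scale in cKO neurons. For Cckbr the difference of log2 changes was -6.90 ± 0.29 (adjusted p = 1.33e-09), for Sez6l -6.05 ± 0.33, for Sprr1a -5.27 ± 0.31 and for Flrt3 -3.13 ± 0.18. Neuropeptide Y (Npy) rose from 0.311 ± 0.306 to 151 ± 149 CPM in control samples, while cKO samples had 9.2 ± 4.28 CPM without and 12.8 ± 6.79 CPM with crush, a difference of -8.46 ± 1.24 that limma-voom did not call. A total of 335 genes differed, 42 with a higher and 293 with a lower crush effect in cKO neurons. The number with a higher effect depended on the test and threshold, with 248 higher and 608 lower by DESeq2 and 5 and 149 at an adjusted p under 0.01. All 48 libraries as separate samples, which counts aliquots as replicates, gave 183 and 570. The median log2 change of the 293 genes was 2.60 for crush in control, 0.52 for crush in cKO, 2.18 for deletion without injury and 0.19 for deletion after crush. The interaction is the difference of these contrasts and shares their samples, so selection for it by itself moves these medians. In a check chosen after the values were seen, genes with a lower effect were taken from 2 animals per group, which gave 22 to 73 genes over the 6 choices, and measured in the other 2. There the medians were 3.65 to 5.90 for crush in control, 0.65 to 1.19 for crush in cKO, 3.38 to 5.11 for deletion without injury and 0.09 to 0.63 for deletion after crush.

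The regeneration-associated list held 24 genes with a lower crush effect in cKO neurons and none with a higher one (29 lower adjusted over the list alone; camera adjusted p = 8.33e-44). The difference missed the threshold for the other 15 of the list, among them Gal (-0.91 ± 0.45; adjusted p = 0.405). In the ATF4 list the effect was lower for 5 of 36 genes (15 adjusted over the list alone; camera adjusted p = 3.12e-08, and adjusted p = 0.129 with an estimated correlation). Examples were Aars (-1.28 ± 0.16), Chac1 (-2.54 ± 0.35) and the amino acid transporter gene Slc7a5 (-1.40 ± 0.25). The crush effect was also lower for 5 of 32 axon cytoskeleton genes, with Tubb6 at -3.46 ± 0.40 and Tuba1c at -2.75 ± 0.35 (camera adjusted p = 0.0218; adjusted p = 0.346 with an estimated correlation). Single genes of other lists also had a lower crush effect, such as the pentose phosphate enzyme gene Taldo1 (-0.64 ± 0.12). With no member called, peptidergic markers, inhibitory and modulatory receptors, oxidative phosphorylation genes and satellite glia markers lay higher and sterol synthesis genes lower as lists, at adjusted p = 0.0218, 0.0218, 2.36e-05, 0.000115 and 0.000547. With an estimated correlation these p were 0.493, 0.141, 0.527, 0.322 and 0.309. Interferon-induced (1 of 19 called, p = 0.0218) and immediate early genes (1 of 14 called, p = 0.0311) lay higher as well, with p = 0.535 and 0.493 with an estimated correlation. Among other-cell markers the log2 crush effect was lower in cKO neurons for Cx3cr1 (-7.09 ± 0.72) and Trbc2 (-5.46 ± 0.66). A lower log2 effect need not mean a lower level after crush. Mean Trbc2 went from 0.0191 to 4.71 CPM in control and from 2.54 to 12.9 CPM in cKO samples. Without the uninjured cKO sample of animal 1 the interaction called 202 genes, and it called 549 with limma-voom. Among genes with a higher crush effect in cKO neurons, Rasd1 (2.74 ± 0.59) lost its call without uninjured control animal 2, uninjured cKO animal 1 or crush control animal 1, 3 or 4 (2.47 to 2.67). Bst2 (2.30 ± 0.53) lost it when any of 10 of the 16 samples was left out (2.06 to 2.43), each uninjured cKO sample among them.

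**Figure D2:**
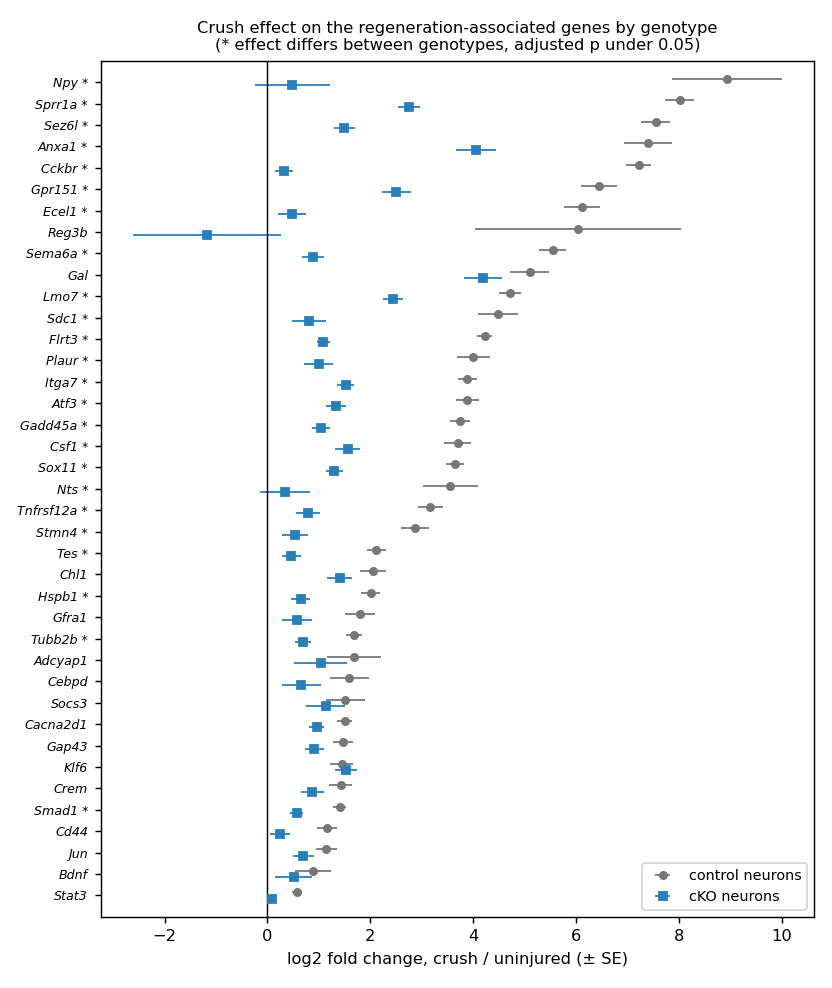
Log2 change with crush (± SE) of the 39 measured regeneration-associated genes in control neurons and in cKO neurons, 4 animals per group; an asterisk marks an interaction adjusted p under 0.05. The 24 genes with an asterisk all had a smaller log2 change in cKO neurons.

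The study's central question was whether losing Tsc2 without injury gives a change like that of an earlier nerve injury. In uninjured neurons, loss of both Tsc2 copies raised Cckbr from 0.395 ± 0.06 to 89.8 ± 8.73 CPM (SD, n = 4), a log2 change of 7.82 ± 0.25 (adjusted p = 1.58e-11). It raised Sprr1a from 4.31 ± 0.8 to 223 ± 31.3 CPM, a change of 5.69 ± 0.25. The keratin gene Krt19 (8.29 ± 0.81), the stress peptide gene Ucn (7.93 ± 0.68), the transcription factor gene Wt1 (7.58 ± 0.69) and Ecel1, a peptidase gene induced by nerve injury (7.31 ± 0.37), were the other leading rises. Among the falls were the itch receptor gene Mrgpra3 (-8.58 ± 1.96), the interleukin-31 receptor gene Il31ra (-5.34 ± 0.89) and Sst, the neuropeptide somatostatin. Sst went from 73.4 ± 51.7 to 0.133 ± 0.101 CPM, a fall that limma-voom did not call. Its level ranged from 15.0 to 139.5 CPM among uninjured control samples and from 0.0206 to 0.248 CPM among uninjured cKO samples. Il31ra rose with crush in cKO neurons (4.06 ± 0.85). A different mix of neuron subtypes among the sorted cells could also give falls of such subtype markers and was not tested. Calca, the precursor gene of the pain peptide CGRP, fell from 10232 ± 4596 to 2557 ± 619 CPM (adjusted p = 0.000153). Deletion changed 3948 genes, 2230 upwards and 1718 downwards, and 1940 of them by more than 2-fold.

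Regeneration-associated genes rose in 31 and fell in 1 of 39 cases without injury (34 up adjusted over the list alone; camera adjusted p = 6.10e-26), with Sez6l at 6.44 ± 0.27 and Flrt3 at 2.67 ± 0.13. The ATF4 response rose in 24 of 36 genes and fell in none (26 adjusted over the list alone; camera adjusted p = 3.69e-14), with Aars at 1.57 ± 0.11 and the stress transcription factor gene Ddit3 at 1.35 ± 0.11. Lysosome genes and targets of the transcription factor TFEB rose in 24 and fell in 1 of 33 cases (24 up adjusted over the list alone; camera adjusted p = 1.69e-08). The lysosomal protease gene Ctsb went from 4838 ± 362 to 11170.1 ± 509 CPM (1.21 ± 0.09 on the log2 scale) and Ctsd rose by 1.02 ± 0.12, whereas the autophagy gene Map1lc3a was the member that fell (-0.89 ± 0.12). Sterol and lipid synthesis genes rose in 11 of 27 cases, with the desaturase gene Scd1 at 0.89 ± 0.14 and the fatty acid synthase gene Fasn at 0.97 ± 0.17. Their camera adjusted p was 0.000245, and 0.127 with an estimated correlation. Glycolysis and hypoxia-inducible genes rose in 8 and fell in 2 of 23 cases, with Slc2a1 at 1.94 ± 0.15 and the hypoxia transcription factor gene Hif1a at 0.77 ± 0.13. For this group the camera adjusted p was 0.00849, and 0.148 with an estimated correlation. Mitochondrially encoded genes rose in 4 of 7 cases (p = 0.0354; p = 0.566 with an estimated correlation). Of 70 nuclear-encoded oxidative phosphorylation genes 13 rose and 3 fell, without a list call (p = 0.252). Other lists without a call were axon cytoskeleton genes (10 up, 4 down of 32; p = 0.344), mTORC1 pathway members (6 up, 2 down of 24; p = 0.317) and cell cycle genes (4 up of 16; p = 0.0687). The deleted gene Tsc2 is itself a member of the mTORC1 list and among its falls.

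Non-peptidergic nociceptor and pruriceptor markers fell in 4 of 17 cases without a list call (median 0.12; camera adjusted p = 0.385). Peptidergic nociceptor markers fell in 5 and rose in 1 of 11 cases (camera adjusted p = 0.000645, and adjusted p = 0.168 with an estimated correlation). Among the falls was the receptor tyrosine kinase gene Kit (-2.75 ± 0.36). Ion channels fell in 16 and rose in 3 of 42 cases, including the acid-sensing channel gene Asic3 (-2.58 ± 0.31), the potassium channel gene Kcnq5 (-3.17 ± 0.44) and the sodium channel gene Scn8a (-1.75 ± 0.24). The channel list had a camera adjusted p of 0.000245, and of 0.102 with an estimated correlation. Presynaptic release genes fell in 7 and rose in 3 of 28 cases without a list call (p = 0.107), among them the vesicle protein genes Syt2 (-2.96 ± 0.30) and Sv2b (-3.50 ± 0.42). Inhibitory and modulatory receptors fell in 7 and rose in 3 of 23 cases (p = 0.0952), with the neuropeptide Y receptor gene Npy2r at -3.38 ± 0.37. Markers of other cells moved beside these groups. Vascular and fibroblast markers rose in 3 of 15 cases (camera adjusted p = 0.0165; adjusted p = 0.119 with an estimated correlation). Flt1, a receptor gene of vascular cells, went from 0.0339 ± 0.0296 to 8.56 ± 4.02 CPM and Acta2 rose by 5.74 ± 0.65. Neutrophil and lymphocyte markers rose in 2 of 3 (p = 0.0215; p = 0.102 with an estimated correlation). Trbc2 rose by 6.92 ± 0.55 and S100a8 by 4.38 ± 0.68. Macrophage markers rose in 2 of 12 cases without a list call (median -0.29; p = 0.383), with Cx3cr1 at 7.35 ± 0.60. Erythrocyte markers lay lower as a list with none of 3 called (p = 0.0382; p = 0.119 with an estimated correlation). Of other-cell markers, 1 of 11 satellite glia and 1 of 11 Schwann cell markers fell (p = 0.195 and 0.605).

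The overlap of the crush and deletion responses was counted next. Of the genes that rose with crush in control neurons, 1265 (60.3%) also rose with deletion in uninjured neurons, and 706 (42.7%) of those that fell also fell. A total of 45 genes moved in opposite directions. Lists of these sizes drawn independently would share 245.5 higher and 149 lower genes and hold 383 opposite ones. Both comparisons use the uninjured control samples, which had the fewest genes detected of the 4 groups. At 1 common depth they had 15900.0 ± 313 genes per library, against 17340.1 ± 321 in uninjured cKO, 16540.0 ± 77.2 in crush control and 16696 ± 833 in crush cKO samples (SD, n = 4). The 40 simulations of unchanged groups against shared controls held 0 calls in either comparison, so they could not show a shared call and were used for the correlation and covariance alone. Across genes, which are not independent replicates, the log2 changes of the 2 comparisons had a correlation of 0.665 against a mean of 0.496 (0.456 to 0.521) in the simulations. Their covariance was 1.44 against 0.343 (0.304 to 0.372). The simulations drew genes independently, each with a dispersion common to all groups. Their ranges therefore leave out shifts of a sample shared across genes and differences in spread between groups. With the 4 control animals split 2 and 2 between the comparisons, in all 6 assignments, 952 to 1089 genes were shared in direction and 15 to 150 were opposite. The covariance was then 0.983 to 1.17 against 0.0263 (-0.0377 to 0.0617) for simulated unchanged groups. The shared genes included Cckbr, Sprr1a, Sez6l, Flrt3, Atf4, Chac1 and Slc2a1 among the rises and Snap25 (-1.04 ± 0.14 with crush, -1.11 ± 0.14 with deletion) and Etv1 (-2.60 ± 0.59 and -2.97 ± 0.60) among the falls. A further 1734 genes were called for crush alone and 1932 for deletion alone, such as Ctsb, whose crush change in control neurons was 0.16 ± 0.09 (adjusted p = 0.271), and Scn10a, whose deletion change was -0.15 ± 0.17 (adjusted p = 0.617).

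**Figure D3:**
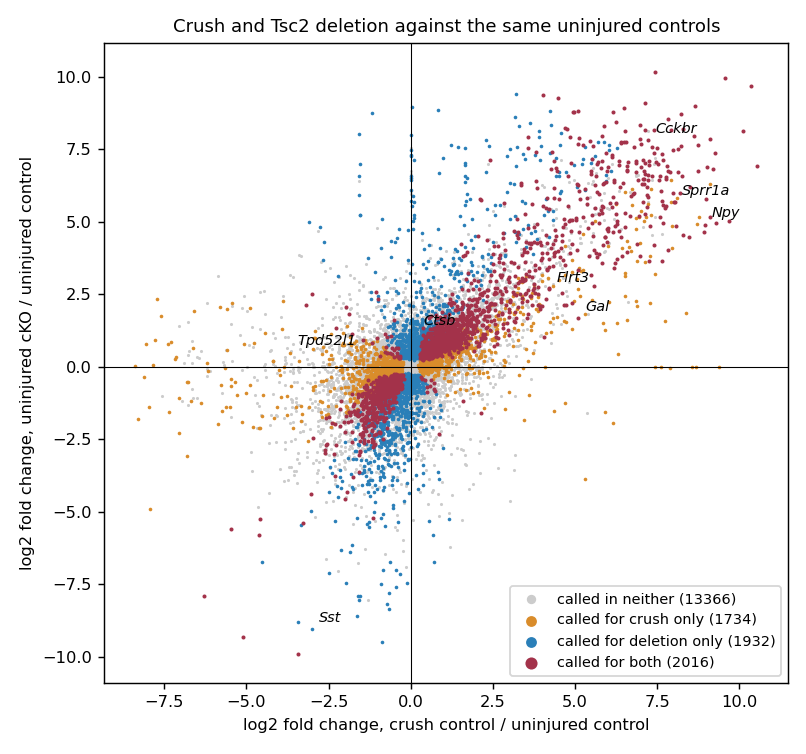
Log2 change with Tsc2 deletion in uninjured neurons against log2 change with crush in control neurons for the 19048 genes tested, coloured by which comparison called them. Of the genes, 2016 were called in both comparisons, 1734 for crush alone, 1932 for deletion alone and 13366 in neither, and both axes use the same uninjured control samples.

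The last comparison asked what losing both Tsc2 copies changed in neurons that had been crushed. Podoplanin (Pdpn) rose by 3.10 ± 0.24 on the log2 scale (adjusted p = 3.30e-06), the lymphocyte antigen gene Ly6e by 3.69 ± 0.37, the annexin gene Anxa3 by 4.26 ± 0.50, the orphan receptor gene Gprc5a by 3.35 ± 0.39 and Ucn by 3.37 ± 0.53. Th, the rate-limiting enzyme gene of catecholamine synthesis and a marker of low-threshold C fibres, was at 730.4 ± 581 CPM in cKO and 21.5 ± 22.7 CPM in control samples (SD, n = 4), a rise of 5.08 ± 0.97 that limma-voom did not call. Crush control animal 1 stood apart from the other 3 at 55.3 CPM of Th. Among uninjured cKO samples Th ranged from 90.6 to 1283.5 CPM. Whether the share of low-threshold C fibres differed between samples was not tested. Asic3 (-2.64 ± 0.31), Kcnq5 (-3.81 ± 0.46), Sv2b (-2.91 ± 0.41), Kit (-2.36 ± 0.36) and the growth factor gene Bdnf (-1.71 ± 0.36) fell. Deletion changed 1256 genes after crush, 644 upwards and 612 downwards, 641 of them by more than 2-fold. Among the 1256 genes, 456 rises and 450 falls were called without injury too, where independent lists would share 75.4 and 55.2.

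Lysosome genes and TFEB targets rose in 16 and fell in 2 of 33 cases after crush (22 up adjusted over the list alone; camera adjusted p = 3.56e-11). Ctsb stood at 5388 ± 583 CPM in control and 11156 ± 1146 CPM in cKO samples, and the lysosomal enzyme genes Ctsa (1.02 ± 0.12), Gla (1.14 ± 0.16) and Neu1 (0.86 ± 0.16) rose. Nuclear-encoded oxidative phosphorylation genes rose in 15 of 70 cases, with Cox4i1 at 0.49 ± 0.08 (31 adjusted over the list alone; camera adjusted p = 3.84e-11, and adjusted p = 0.328 with an estimated correlation). Mitochondrially encoded genes rose in 6 of 7 cases (p = 2.86e-05; p = 0.226 with an estimated correlation). The ATF4 response rose in 3 of 36 cases, with Ddit3 at 1.22 ± 0.11 and the serine synthesis gene Phgdh at 1.75 ± 0.24 (camera adjusted p = 6.56e-07; adjusted p = 0.091 with an estimated correlation). Glycolysis and hypoxia-inducible genes rose in 3 of 23 (p = 0.0106; p = 0.192 with an estimated correlation). Ion channels fell in 5 of 42 cases (p = 0.00107; p = 0.119 with an estimated correlation). Presynaptic release genes fell in 5 of 28 with 1 rise (p = 0.0136; p = 0.119 with an estimated correlation), and peptidergic markers in 4 of 11 (p = 0.0352; p = 0.512 with an estimated correlation). Regeneration-associated genes rose in 4 and fell in 3 of 39 cases without a list call (camera adjusted p = 0.318), with Ecel1 at 1.67 ± 0.28 and Cckbr at 0.93 ± 0.17. Beside these groups, vascular and fibroblast markers rose in 2 of 15 cases (7 adjusted over the list alone; camera adjusted p = 5.64e-05), with Flt1 at 4.22 ± 0.57 and Acta2 at 3.86 ± 0.58. Neutrophil and lymphocyte markers rose in 2 of 3 (p = 0.00968; p = 0.091 with an estimated correlation). Satellite glia markers lay higher (p = 0.0249; p = 0.541 with an estimated correlation) and erythrocyte markers lower (p = 0.0136; p = 0.091 with an estimated correlation) as lists, with no member called. The number of calls was 834 with the glial covariate, 2241 with DESeq2 and 1993 with all 48 libraries as separate samples, which counts aliquots as replicates.

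**Figure D4:**
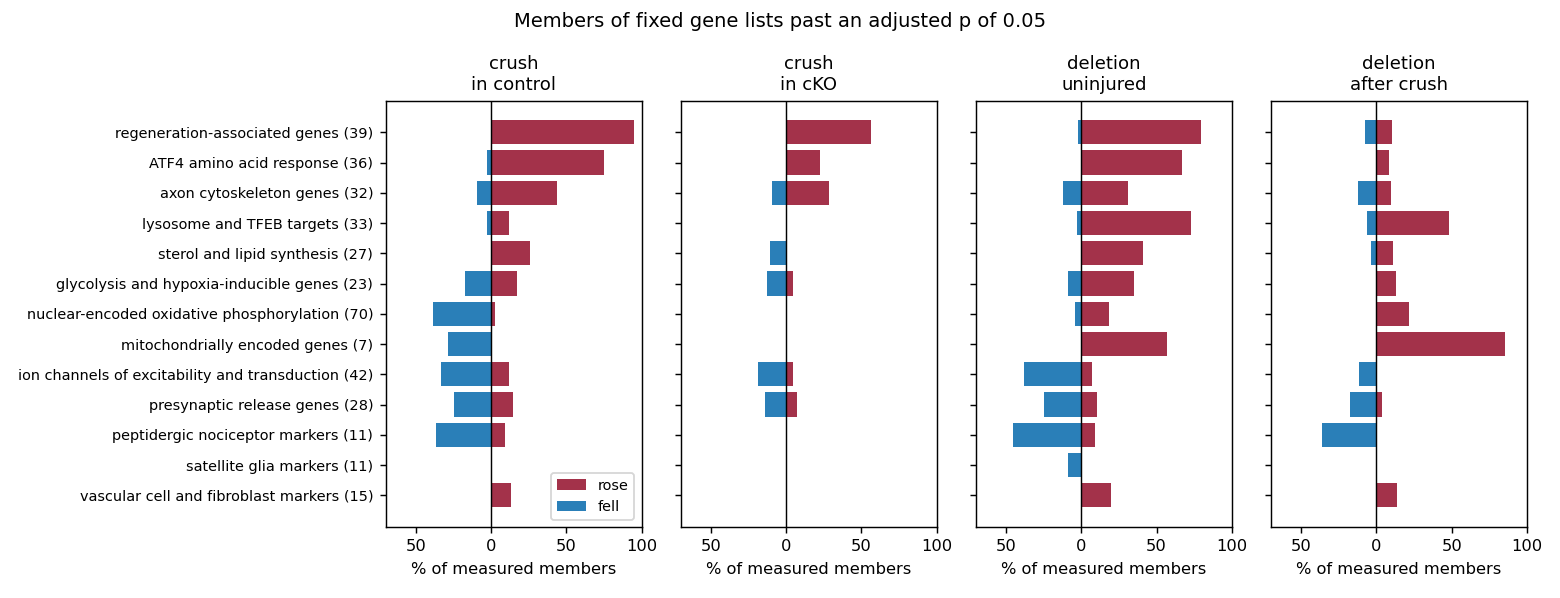
Percent of measured members of 13 fixed gene lists that rose or fell (edgeR adjusted p under 0.05) in each of 4 comparisons. Regeneration-associated and ATF4 response genes rose with crush and with deletion in uninjured neurons, and lysosome genes rose with deletion on both sides.

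Over the 135 tests of 27 lists in 5 comparisons, camera made 55 calls, of which 9 held with an estimated correlation. The regeneration-associated list held with crush in either genotype, with deletion in uninjured neurons and in the interaction. The others were the ATF4 list with crush in control and with deletion in uninjured neurons, the lysosome list with deletion on both sides, and the vascular and fibroblast list with deletion after crush. In 14 of the 135 tests, none of them past the threshold, a list's median, mean and test differed in sign. They were immediate early genes with crush in control neurons, endoplasmic reticulum chaperones with crush in cKO neurons, and non-peptidergic, large-fibre and macrophage markers with deletion in uninjured neurons. In the interaction they were non-peptidergic markers, presynaptic genes and vascular markers. With deletion after crush the receptors, mTORC1 members, endoplasmic reticulum chaperones, pentose phosphate pathway, ribosomal proteins and macrophage markers did so.

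The authors' deposited table of comparisons listed 8600 genes. It gave adjusted p under 0.05 for 4762 genes after crush in control neurons, 5154 with deletion in uninjured neurons and 6888 in crushed cKO neurons. The authors' deposited table does not name its reference group, which was inferred to be the uninjured control from its fold changes. All 8600 genes of the authors' deposited table have at least 1 adjusted p under 0.05 in it, and 2865 genes tested here with a mean CPM above 10 are not listed. Over the listed genes, which were thus selected for being called, its fold changes for the first 2 correlated at 0.984 and 0.985 with crush in control and deletion in uninjured neurons as computed here. Those for crushed cKO neurons correlated at 0.990 with crushed cKO against uninjured control samples, a contrast fitted for this purpose alone. Of its calls, 3476, 3663 and 5598 were also called here, all in the same direction.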

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

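Among the tests given here, those for an uninjured library with a wrong label and for lower RNA capture were chosen after the result was seen. The crush effect differed between genotypes for 335 genes by the interaction test, and 28 of the genes named in the text were among them. The change with crush on the log2 scale was lower in cKO than in control neurons, by the interaction value, for the secreted or receptor genes Npy (-8.46), Cckbr (-6.90), Inhbb (-5.11), Ucn (-4.56) and Cx3cr1 (-7.09). It was also lower for Sez6l (-6.05), Ecel1 (-5.64), Krt19 (-5.55), Trbc2 (-5.46), Sprr1a (-5.27), Wt1 (-4.85) and Flt1 (-3.71). Further values were those of Anxa1 (-3.35), Flrt3 (-3.13), Anxa3 (-2.87) and Lmo7 (-2.28), and of the tubulin genes Tubb6 (-3.46) and Tuba1c (-2.75). Transporter and enzyme genes with a lower crush effect were Slc6a4 (-2.94), Slc7a5 (-1.40), Slc2a1 (-1.04), Chac1 (-2.54), Aars (-1.28), Mthfd2 (-0.91) and Taldo1 (-0.64), besides the transcription factor gene Atf4 (-1.001). It was higher in cKO neurons for Bst2 (2.30) and Rasd1 (2.74). Flt1 had an adjusted p of 0.0451 for the interaction in edgeR, and 0.137 with the replicate block. Its call was lost when any of 13 of the 16 samples was left out, with values of -4.11 to -3.29.

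In the CPM of the genes plotted or given as group means and in depth and genes detected, 3 samples stood far from the other 3 of their group by Dixon's test, out of 60 groups tested, where chance gives about 1 in 20. They were Kcnmb1 in the crush cKO sample of animal 4 (10.5 CPM), Sst in the crush control sample of animal 3 (34.6 CPM) and Th in the crush control sample of animal 1 (55.3 CPM).

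Of technical explanations for crush-like expression in uninjured cKO neurons, seen in 1971 genes called in the same direction for crush in control and for deletion without injury, chance values of shared control samples are argued against by the split of the controls, where the lowest covariance of log2 changes over the 6 assignments was 0.983 and that of simulated groups sharing all controls reached 0.372. The simulated value leaves out shifts of a sample shared across genes. Glial RNA in the sort, which the reporter gate should remove, was tested with the mean of satellite glia and Schwann cell markers as a covariate. With this covariate 1655 genes were still called in both comparisons, which argues against glial RNA that follows this mean. The most abundant satellite glia gene, Fabp7, had 212 ± 48 CPM in uninjured control and 195 ± 40.2 CPM in uninjured cKO samples. The mean log2 CPM of satellite glia markers was 5.00 and 4.66 in these groups, and that of Schwann cell markers 2.08 and 2.83. These means moved in opposite directions and partly cancel in the covariate, so RNA of satellite glia or of Schwann cells alone was not tested. The covariate holds no vascular or immune markers, so RNA of those cells was not tested as an explanation. The mean log2 CPM of vascular and fibroblast markers was 0.58 in uninjured control and 2.21 in uninjured cKO samples. A crush library with an uninjured label would mask crush calls in cKO neurons, but leaving out 1 uninjured cKO sample gave at most 724 such calls against 1034 with all 4, and Gal was at most 1744.7 CPM in uninjured cKO and at least 9583 CPM in crushed samples. Lower RNA capture in all uninjured control samples, which had the fewest genes detected, is not addressed by the split, but capture acting on genes by their level is argued against for the regeneration-associated list, whose median log2 change was 3.56 with crush and 2.13 with deletion where the highest of 10000 random lists matched on level reached 0.308 and 0.382. For the other shared genes it stays open, since 94.97% of those with a mean below 1 CPM rose against 48.2% at 100 CPM or more, and beside it stand 2 hypotheses, a response to Tsc2 loss that overlaps the injury response and an untested effect of the contralateral crush on uninjured cKO neurons.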

How the results depend on the processing

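Fits without 2 shallow aliquots, without genes near Tsc2 and the alternatives of the overlap other than RLE size factors, a mean CPM of at least 10, a 2-fold change and split controls were chosen after the data had been seen. No list call, and no call of a gene taken by the naming rule, reversed its direction under any alternative run. Directions of the other called genes were not compared. Which direction held more calls was not stable for crush in cKO, where 490 rises and 544 falls became, for example, 347 and 321 with the glial covariate and 349 and 288 without crush cKO animal 4, and where rises led in 11 and matched falls in 2 of 24 alternatives. For deletion after crush falls led in 4 of 24, such as 470 rises and 490 falls without crush control animal 1. With adjusted p under 0.05 and a change over 2-fold, the counts were 1710, 457, 1940 and 641 for crush in control, crush in cKO, deletion without injury and deletion after crush, and 846 for the overlap. With adjusted p under 0.01 they were 2002, 431, 2105 and 479, with 154 for the interaction and 962 for the overlap. The glial covariate left 668 calls for crush in cKO and 834 for deletion after crush. DESeq2 gave 1782, 2241 and 856 for crush in cKO, deletion after crush and the interaction. Taken as 48 samples, the libraries gave 1993 and 753 for deletion after crush and the interaction. That fit counts technical aliquots as replicates, so its counts do not rest on the animal as the replicate. Limma-voom gave 1563 and 549 for crush in cKO and the interaction; the causes were not tested. Leaving out 1 sample at a time gave 2753 to 3664 calls for crush in control, 618 to 885 for crush in cKO and 2932 to 4008 for deletion without injury. It gave 928 to 1054 for deletion after crush, 202 to 485 for the interaction and 1538 to 2001 for the overlap, with fewer samples in each fit. Splitting the controls, which leaves 2 per comparison, gave overlaps of 1089, 957, 958, 952, 978 and 1015. Of 55 list calls, 9 held with an estimated correlation. With the replicate block the calls were 3814, 1104 and 288 for crush in control, crush in cKO and the interaction. They kept 3289 of the 3750, 862 of the 1034 and 226 of the 335 genes called without the block. With the number as a block across genotypes, where same-numbered samples had correlations down to 0.0713, they were 3909 and 1314 for deletion without injury and after crush. Among list calls and the calls printed for single genes taken by the naming rule, the block changed only the neutrophil and lymphocyte list and the interaction of Flt1. Without aliquots 3C and 4C of crush cKO the 5 counts were 3755, 1144, 3933, 1356 and 309, and without genes within 20 Mb of Tsc2 3659, 1013, 3817, 1182 and 325. Of single-gene results under an alternative, 7523 stayed the same, uncalled results of Tsc2 among them, and 624 lost their call. Another 4, all of Tsc2 with crush, had no call and changed sign. Of list results 578 stayed, 69 lost and 16 gained a call, and 12 without a call changed direction. Depth limits low genes, and the shallowest library held 5159353 counts.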

Other observations

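The gene family tests, the count of deletion calls near Tsc2, the Atp6v0c copies, the comparison of aliquot variances and the divisions of whole animals were chosen after the result was seen. Gene families sharing a symbol stem were tested with camera, 200 families in 5 comparisons, and 12 of 1000 tests passed an adjusted p of 0.05. None of the families named here did so with an estimated correlation. After crush in control neurons, 8 of 14 measured sodium channel (Scn) genes fell, among them the auxiliary subunit gene Scn2b (-1.47 ± 0.38), at a camera adjusted p of 0.00249, and 0.406 with an estimated correlation. Intraflagellar transport genes, which build primary cilia, fell in 7 of 14 cases, including Ift80 (-0.98 ± 0.17) and Ift122 (-0.91 ± 0.15), at adjusted p = 0.00983, and 0.406 with an estimated correlation. After crush in cKO neurons, 6 of 47 genes named for interleukins and their receptors rose, with Il4ra at 1.44 ± 0.15 and Il1r1 at 1.88 ± 0.20 (adjusted p = 0.0202, and 0.184 with an estimated correlation). With deletion after crush, 17 of 75 Atp genes rose and 7 fell (adjusted p = 0.0401, and 0.995 with an estimated correlation). Subunits and partners of the proton pump of lysosomes, which were not tested on their own, were among the rises, such as Atp6ap2 (0.68 ± 0.08) and Atp6v1g1 (0.56 ± 0.08). The pump subunit genes Atp6v0c (-2.29 ± 0.18) and Atp6v1g2 (-0.49 ± 0.10) were among the 7 falls. The named genes of these families were chosen after their values were seen.

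Deletion calls after crush were more frequent near Tsc2 on chromosome 17, with 54 of 538 tested genes called within 20 Mb against 1177 of 18127 on other chromosomes, an odds ratio of 1.61 (Fisher's exact test, p = 0.00196, 0.0130 adjusted over the regions and comparisons tested). Within 20 Mb the odds ratio was 1.08 without injury and 0.814 for crush in control neurons. The window from 35 to 40 Mb, which holds major histocompatibility genes, was picked for the highest share of calls among the 19 bins of 5 Mb on the chromosome, with 25 of 90 genes after crush (odds ratio 5.54; p = 8.27e-09 with Bonferroni adjustment over the bins) and 34 of 90 without injury (2.31; p = 0.00420); after crush H2-Q2 (6.90 ± 0.74) and H2-D1 (1.19 ± 0.19) rose while H2-T24 fell (-3.70 ± 0.84). Without that window the odds ratio within 20 Mb after crush was 0.997 (0.656 to 1.46), a value lowered by the choice of the window, so a smaller excess stays open. A strain haplotype travelling with the Tsc2 alleles in this mixed background is a candidate explanation for the window, and an effect of the deletion on these genes stays open because the allele and its surroundings cannot be separated here. Atp6v0c, next to Tsc2, fell by 2.29 ± 0.18 after crush, whereas its processed copy Atp6v0c-ps2 rose by 1.26 ± 0.09 and the sum of all copies by 0.57. Reads moving between copies may account for that fall. The sum cannot tell this from a real fall, because Atp6v0c held 14.6 and Atp6v0c-ps2 57.1 of the 71.9 CPM on average.

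More genes were detected per library in uninjured cKO than in uninjured control samples, 19260 ± 487 against 17468 ± 379 (SD, n = 4; exact two-sided permutation test, p = 0.0286, the smallest possible). Depth is argued against as the whole cause, since after thinning every library to 5159353 counts the difference was 1440.1 against 1791.8 before. Lower capture of RNA in control aliquots is a possible explanation that was not excluded, because aliquots of an animal varied more in uninjured control than in uninjured cKO samples at every expression level, with median variance ratios of at least 1.79. After crush cKO and control samples differed by 161 genes (p = 0.914), and at the thinned depth crush control samples exceeded uninjured control samples by 640.0 (p = 0.0286), so the uninjured control samples were lowest. A broader set of expressed genes after Tsc2 loss or injury could give the same pattern and was not separated from lower capture.

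Other divisions of the same samples rarely called genes. Without regard to pairs, the share of divisions with as many calls was under 0.05 for each of the 4 counts between 2 groups. It was the smallest share that 35 divisions allow. It argues against a chance division as the origin of these counts, and for the crush counts it does so only if the samples are not paired. The real division was the only 1 of 35 with as many calls for crush in control (3750, highest other 6), crush in cKO (1034, highest other 4), deletion without injury (3948, highest other 0) and deletion after crush (1256, highest other 1). For the interaction, with genotypes exchanged on each side separately, 1 of 60 divisions gave as many calls (335, highest other 2). If equal numbers pair the samples of a genotype, which is uncertain for the control samples, both sides of an animal must be exchanged together. Then 1 of the 35 divisions of the 8 animals gave as many calls (335, highest other 0). Exchanged genotypes also mix the deletion effect itself into the spread within groups, which can leave few calls whether or not crush and deletion interact. Neither exchange can therefore tell the interaction count from chance. For the crush counts in such pairs, 8 of the 35 divisions part all 4 pairs as the real one does, and these are too few for a share under 0.05. Among them the highest other count was 1 for crush in control and 0 for crush in cKO.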
